A study of Saccharolobus islandicus LAL14/1 with 12 samples.

How the data were processed

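RNA was taken from cultures of Saccharolobus islandicus LAL14/1 with a plasmid for arabinose-inducible gp21 of virus SIRV2, or with the empty plasmid, at 0, 6 and 12 h after 0.2% D-arabinose. Per the labels, the shaken cultures grew at 78 °C in SCV medium, total RNA was extracted with TRI Reagent, and libraries were made and sequenced by an outside service from 2 independent biological replicates per plasmid and time. The 12 libraries were placed in 6 groups by the plasmid and time in the labels.

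The authors deposited raw counts of reads per gene for each library, and the tools named in the submitters' processing notes are Bowtie2, featureCounts, DESeq2 and edgeR, without versions. Aligner settings, strand option and genome build are not given in the sources used here. Per the file headers, each gene has a start, end and strand on the LAL14/1 chromosome, and gp21 is counted on a separate sequence. The authors' deposited DESeq2 table pools 6 and 12 h and gives log2 fold changes with standard errors, a score (the Wald statistic) and p-values with adjusted p-values. The authors' deposited edgeR table for 0 h gives log2 fold changes, log2 CPM and an unadjusted p-value per gene. Of these tables the log2 fold changes, their p-values and the product and domain descriptions of genes were used.

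Counts were tested in edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr on the 6 groups (minimum count 10) and robust quasi-likelihood fits of 6 group means over all 12 libraries, with 6 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over the 2619 of 2651 genes tested, with a threshold of 0.05. SE is the size of the log2 fold change fitted without a prior count, divided by the square root of F. The printed fold changes include the small prior count of edgeR, so the 2 can differ for genes with low counts. The contrasts were gp21 against control at each time, the differences of those contrasts between times, and the changes over time within each strain. The common biological coefficient of variation was 0.130 and the median prior degrees of freedom 6.57. Total counts per library were 17033337 to 22299061, TMM factors ran from 0.832 to 1.23, the 10 most abundant genes took 25.2% to 35.9% of the reads, ribosomal RNA 0.014% to 0.044% and tRNA 0.055% to 0.15%. Counts of replicates differed by more than sampling noise in every group (chi-square per degree of freedom 19.3 to 114), so no library was treated as a copy of another. The first 3 principal components of log CPM held 43.6%, 24.2% and 19.7% of the variance. On simulated data with 100 genes changed 2-fold and 100 changed 1.5-fold, the test found 95% and 68% of them at 0 h, 96% and 68% at 6 h and 96% and 63% at 12 h. False calls made up 4.12%, 8.38% and 6.47% of the calls there, over 2614, 2615 and 2613 genes. Part of the 1.5-fold changes was thus missed in that setting, and smaller changes were not simulated. Far more genes were called in the data than were changed there, which loosens the Benjamini-Hochberg cut-off, so these shares need not hold for the data.

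Gene lists were 24 sets of patterns on product descriptions, of which 23 had 3 or more tested genes. Members whose description pointed to another function were taken out by hand (142 exclusions), and SiL_1169 was added to cell division for its position beside cdvB. The pattern for ribosomal RNA matched only protein genes, which were taken out by hand, as the 3 ribosomal RNA rows have no description; that list was left without members, and ribosomal RNA is given as the share of reads above. Lists were tested with camera in limma 3.58.1 on log CPM (prior count 2) with a preset correlation of 0.01, and Benjamini-Hochberg adjustment ran over 69 tests, 23 lists at 3 times. Camera with an estimated correlation and fry were run beside it. Genes shared between 6 and 12 h were set against independent lists with a one-sided Fisher's exact test.

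Named genes were, at 6 and 12 h, the 10 with the highest and the 10 with the lowest log2 fold change among those past the test, with a mean of 10 CPM or more in at least 1 of the groups and both gp21 libraries on the same side of both control libraries. At 0 h the 3 highest and 3 lowest were taken by that rule, and for the other contrasts 3 and 3 without the last condition. Transposases and ribosomal RNA were left out there because copies share reads. Always named were gp21, SiL_0190, the cdv and other ESCRT-III genes and the 3 orc1/cdc6 genes, and from each list up to 4 members with the smallest adjusted p. Values of these genes in further contrasts (SiL_2265 to SiL_2271 at 0 h and in the differences between times, SiL_1374 and genes of SiL_0976 to SiL_0987 at 0 h, gp21 and SiL_0977 over time with gp21, 3 arabinose genes over time in control, CPM of merI) were chosen after they were seen.

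The grouping, contrasts, test, lists, rule for named genes and most alternatives were fixed before the data were examined. Exclusions from lists and the addition of SiL_1169 were made after the descriptions were read. Alternatives were DESeq2 1.42.0 size factors and Wald test, total counts, no filter or a stricter filter (10 CPM in 2 libraries), fits that were not robust, fits of only the groups compared, a replicate block, ribosomal RNA left out, an absolute log2 fold change of 1 or more, and each library left out in turn. Total counts without SlaA (SiL_1604) and lists without exclusions by hand were added after the data were seen. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. A planned test of a promoter motif needs the genome sequence, which was not used here.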

Results

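RNA was sequenced from Saccharolobus islandicus LAL14/1, a thermoacidophilic archaeon grown at 78 °C. The cells carried either a plasmid with gene gp21 of the rod-shaped virus SIRV2 or the empty plasmid. Total RNA was extracted, but ribosomal RNA took only 0.014% to 0.044% of the counted reads, so the libraries do not show its share of total RNA. The gp21 product is a ribbon-helix-helix transcription factor, and the comparisons ask which host transcripts differ when the viral gene is expressed from an inducible plasmid. Cultures were sampled 0, 6 and 12 h after D-arabinose was added to 0.2%, with 2 independent biological replicates per plasmid and time, which gives 12 libraries in 6 groups. Each library held between 17033337 and 22299061 reads counted on genes, and 2619 of 2651 genes had enough reads to be tested. Log CPM values correlated across genes at 0.992 to 0.996 between replicates and at 0.888 to 0.990 between groups, where genes are not independent replicates. The S-layer gene SlaA (SiL_1604) alone took 11.3% to 23.7% of the reads of a library. Fold changes below are log2 ± SE with n = 2 libraries per group, CPM values are means ± SD of 2 libraries, and adjusted p-values come from edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment.

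The gp21 transcript was higher with the gp21 plasmid at all 3 times. It stood at 68.3 ± 3.11 CPM at 0 h, 63.7 ± 1.79 at 6 h and 113 ± 39.1 at 12 h in cells with the gp21 plasmid. Cells with the empty plasmid had 8.14 ± 0.584, 4.93 ± 1.85 and 4.72 ± 0.726 CPM. The log2 fold change of gp21 over control was 3.07 ± 0.25 at 0 h, 3.67 ± 0.26 at 6 h and 4.58 ± 0.27 at 12 h (adjusted p = 4.4e-07, 1.7e-07 and 2.2e-08). Within the gp21 strain, the transcript at 6 h differed from that at 0 h by -0.10 ± 0.21 (adjusted p = 0.68), and at 12 h by 0.72 ± 0.21 (adjusted p = 0.010). The 12 h rise depended on 1 library, since without gp21 replicate 2 of 12 h it was 0.32 and the call was lost (adjusted p = 0.22, against 8.1e-04 to 0.22 over all alternatives). With total counts the 6 h change was 0.38 (adjusted p = 0.13), of the opposite sign. The labels give the first time as 0 h post induction without saying whether it was sampled before D-arabinose was added, so it is not known to be an uninduced level. SiL_0190, the host gene whose product resembles gp21, was lower with gp21 at 0 h (-0.96 ± 0.14) and 12 h (-1.14 ± 0.15), and its difference of 0.10 ± 0.14 at 6 h did not pass the test (adjusted p = 0.56). The gp21 entry (SIRV2gp21) spans 178 bases and SiL_0190 spans 177, and how reads matching both were assigned is not given in the sources used here, so the low gp21 counts of the empty-plasmid libraries are uncertain.

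**Figure D1:**
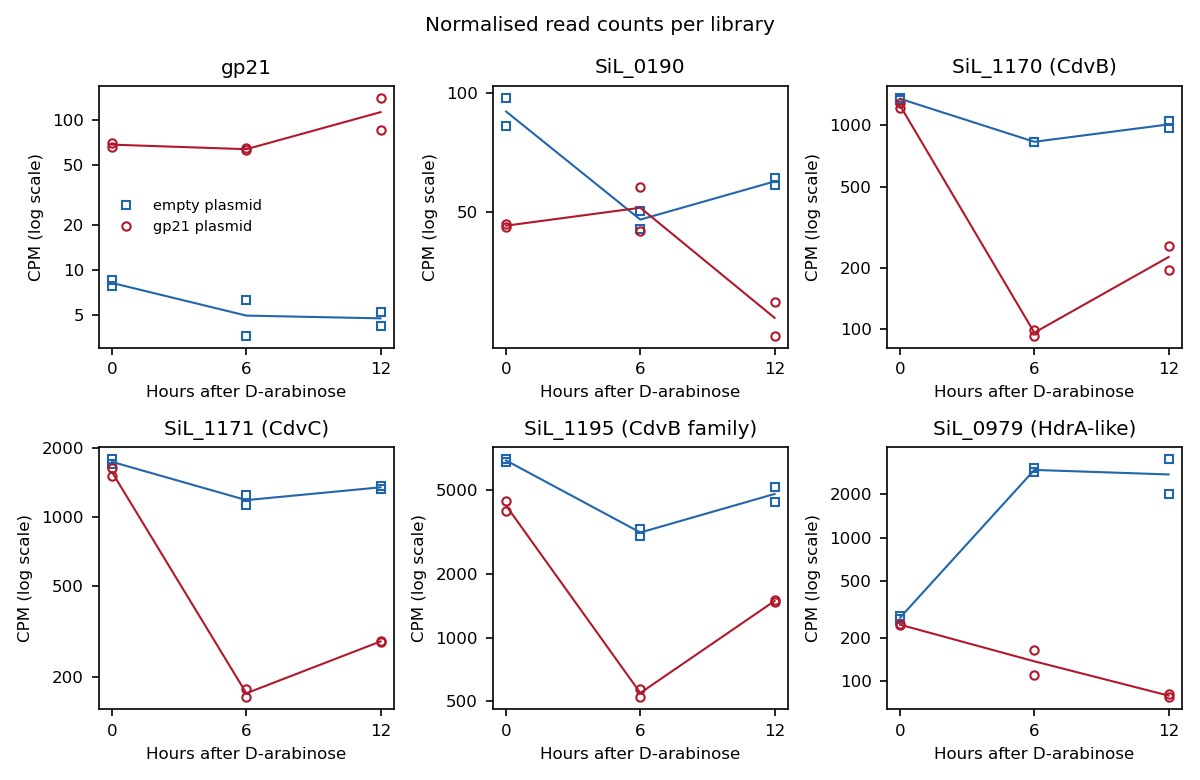
Normalised read counts (CPM, log scale) of 6 genes against hours after D-arabinose; circles are the 2 libraries with the gp21 plasmid, squares the 2 with the empty plasmid, and lines join group means. The gp21 transcript lay at 68.3 CPM with the gp21 plasmid at 0 h, while SiL_1170 (CdvB) stood at 96.4 CPM with gp21 and 828 CPM without it at 6 h.

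At 6 h, genes of the cell division machinery and a sulfur-oxidation gene cluster were far lower with gp21 than with the empty plasmid. The transcript of cdvB (SiL_1170, chromosome positions 1118914 to 1119693, plus strand), which encodes the ESCRT-III protein of the division ring, stood at 96.4 ± 4.59 CPM against 828 ± 0.244 CPM, a log2 fold change of -3.10 ± 0.13. Its neighbour cdvC (SiL_1171), which encodes the Vps4-type ATPase that remodels that ring, was lower by the same test (-2.81 ± 0.10), as was SiL_1169 (-2.19 ± 0.13), an unnamed gene at the position that cdvA takes in related species. The other ESCRT-III family genes were lower too, SiL_1195 at -2.52 ± 0.11, SiL_1391 at -1.56 ± 0.14 and SiL_1541 at -1.43 ± 0.095 (adjusted p at most 1.5e-06 over the 6 division genes). In the heterodisulfide reductase-like cluster SiL_0976 to SiL_0985, whose relatives take part in sulfur oxidation, the lowest was SiL_0978 (-4.73 ± 0.29). There the subunit A gene SiL_0979 (-4.44 ± 0.25) stood at 137 ± 37.4 CPM against 2967 ± 141, the subunit B genes SiL_0976 and SiL_0980 differed by -3.89 ± 0.21 and -3.63 ± 0.18, and the subunit C genes SiL_0977 and SiL_0981 by -4.51 ± 0.27 and -3.40 ± 0.17. The cluster's dihydrolipoamide dehydrogenase SiL_0985 (-4.10 ± 0.16) and peroxiredoxin SiL_0984 (-3.93 ± 0.16), the sulfide-quinone oxidoreductase SiL_0071 (-3.95 ± 0.53) and the HerA-type helicase gene SiL_0017 (-3.11 ± 0.16) completed the 10 lowest. Among the highest were genes of sulfate assimilation, with the phosphoadenylylsulfate reductase SiL_2268 at 4.52 ± 0.23, sulfite reductase SiL_2269 at 3.55 ± 0.15, sulfate adenylyltransferase SiL_2267 at 3.16 ± 0.24 and sulfurtransferase SiL_2271 at 3.77 ± 0.30. Their neighbours SiL_2270 (2.66 ± 0.29) and SiL_2265 (2.57 ± 0.18) were also among the 10 highest, although control levels of SiL_2268 were only 0.866 CPM. These 6 genes were already higher with gp21 at 0 h, at 3.51 ± 0.16 for SiL_2268, 3.52 ± 0.13 for SiL_2269, 3.33 ± 0.19 for SiL_2267, 2.79 ± 0.25 for SiL_2271, 2.95 ± 0.23 for SiL_2270 and 2.80 ± 0.15 for SiL_2265. From 0 to 6 h the difference rose for SiL_2268 (1.01 ± 0.30, adjusted p = 0.0087) and SiL_2271 (0.98 ± 0.39, adjusted p = 0.038), and no change of it was called for the other 4. Both calls were lost when some single libraries were left out. With 1 library left out the rise ran from 0.846 to 1.16 for SiL_2268 and from 0.497 to 1.61 for SiL_2271. The pair SiL_0751 and SiL_0752, described as OB-fold proteins with a zinc ribbon, were higher at 2.64 ± 0.16 and 2.66 ± 0.14, as was SiL_2552, which has no described function (2.58 ± 0.20). Of the 3 orc1/cdc6 initiator genes, SiL_1733 was lower (-1.50 ± 0.085), SiL_1228 was slightly lower (-0.46 ± 0.11) and SiL_0002 was slightly higher (0.50 ± 0.14). The SiL_1228 call was lost with total counts (-0.22, adjusted p = 0.15, against 0.0012 to 0.15 over all alternatives). The call of SiL_0002 ended when control replicate 1 or gp21 replicate 1 was left out (adjusted p = 0.051 and 0.053, against 4.9e-04 to 0.053 over all alternatives).

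The tests called 818 genes higher and 751 lower at 6 h, of which 241 and 208 had an absolute log2 fold change of 1 or more. Scaling by total counts instead of TMM shifted the median by 0.23 and gave 1158 higher and 494 lower. At that time the mean TMM factor was 1.18 with gp21 and 1.00 without, and SlaA took 12.7% ± 2.04 and 18.3% ± 1.21 of the reads (SD, n = 2).

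Among the gene lists, cell division, DNA replication, chromosome organisation and nucleotide synthesis were lower with gp21 at 6 h. Of 6 cell division genes, 6 were lower, 0 higher and 0 not called, or 6 and 0 adjusted over the list alone. For cell division genes, camera gave adjusted p = 2.0e-05, and adjusted p = 0.55 with an estimated correlation. Their median was -2.36. Of 25 DNA replication genes, 17 were lower, 1 higher and 7 not called, or 17 and 1 adjusted over the list alone. For DNA replication genes, camera gave adjusted p = 1.3e-04, and adjusted p = 0.55 with an estimated correlation. Reverse gyrase SiL_1121 was at -2.13 ± 0.10, the GINS-type factor SiL_1226 at -2.08 ± 0.18 and flap endonuclease SiL_1811 at -1.31 ± 0.10. Of 29 nucleotide synthesis genes, 19 were lower, 4 higher and 6 not called, or 19 and 4 adjusted over the list alone. For nucleotide synthesis genes, camera gave adjusted p = 2.5e-04, and adjusted p = 0.55 with an estimated correlation. The purine genes SiL_1379 (amidophosphoribosyltransferase, -2.67 ± 0.20), SiL_1378 (-2.53 ± 0.17), SiL_1377 (-2.23 ± 0.17) and SiL_1383 (-1.81 ± 0.14) led that list. Of 6 chromosome organisation genes, 4 were lower, 0 higher and 2 not called, or 4 and 0 adjusted over the list alone. For chromosome organisation genes, camera gave adjusted p = 0.022, and adjusted p = 0.55 with an estimated correlation. The 4 lower genes were the SMC-type SiL_0016 (-2.18 ± 0.15), the segregation genes segA (SiL_1936, -1.44 ± 0.16) and segB (SiL_1935, -1.58 ± 0.18) and the nucleoid gene alba (SiL_1120, -0.65 ± 0.092). Of 32 DNA repair and exchange genes, 13 were lower, 6 higher and 13 not called, or 13 and 6 adjusted over the list alone. For DNA repair and exchange genes, camera gave adjusted p = 0.058. Without exclusions by hand that p was 0.047. The nuclease gene nurA (SiL_0094) was at -1.50 ± 0.12 and the Holliday junction resolvase SiL_0933 at -1.53 ± 0.14.

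Genes for translation, amino acid synthesis and transcription were lower as well at 6 h. Of 66 ribosomal protein genes, 44 were lower, 1 higher and 21 not called, or 46 and 1 adjusted over the list alone. For ribosomal protein genes, camera gave adjusted p = 8.0e-07, and adjusted p = 0.55 with an estimated correlation. Their median was -0.58, or -0.35 with total counts, and L5 (SiL_1291) was at -1.77 ± 0.19. Of 35 translation factor and tRNA ligase genes, 21 were lower, 3 higher and 11 not called, or 22 and 3 adjusted over the list alone. For translation factor and tRNA ligase genes, camera gave adjusted p = 1.9e-04, and adjusted p = 0.55 with an estimated correlation. Phenylalanyl-tRNA synthetase SiL_1877 was at -1.68 ± 0.13. Of 49 amino acid synthesis genes, 32 were lower, 7 higher and 10 not called, or 33 and 7 adjusted over the list alone. For amino acid synthesis genes, camera gave adjusted p = 3.8e-04, and adjusted p = 0.55 with an estimated correlation. Argininosuccinate lyase SiL_1374 was at -1.96 ± 0.17. Of 25 transcription machinery genes, 15 were lower, 5 higher and 5 not called, or 15 and 5 adjusted over the list alone. For transcription machinery genes, camera gave adjusted p = 0.029, and adjusted p = 0.55 with an estimated correlation. That call ended without exclusions by hand (adjusted p = 0.087).

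Toxin-antitoxin genes, fatty acid genes and transposases were higher at 6 h. Of 39 toxin-antitoxin genes, 21 were higher, 4 lower and 14 not called, or 21 and 4 adjusted over the list alone. For toxin-antitoxin genes, camera gave adjusted p = 0.0077, and adjusted p = 0.55 with an estimated correlation. The vapC-like SiL_2040 was at 1.16 ± 0.12, although SiL_1569, which encodes an antitoxin of the ribbon-helix-helix family, was lower at -1.85 ± 0.15. Of 52 fatty acid and acyl-CoA genes, 25 were higher, 6 lower and 21 not called, or 25 and 6 adjusted over the list alone. For fatty acid and acyl-CoA genes, camera gave adjusted p = 0.0065, and adjusted p = 0.55 with an estimated correlation. Acetyl-CoA synthetase SiL_0747 was at 1.48 ± 0.11. Of 27 transposase genes, 15 were higher, 2 lower and 10 not called, or 15 and 2 adjusted over the list alone. For transposase genes, camera gave adjusted p = 0.038, and adjusted p = 0.55 with an estimated correlation. Transposase copies can share reads, and the XerD-type integrase SiL_1618 was lower at -2.09 ± 0.10. The lists that follow did not pass. Of 28 CRISPR-Cas genes, 14 were higher, 7 lower and 7 not called, or 14 and 7 adjusted over the list alone. For CRISPR-Cas genes, camera gave adjusted p = 0.084. Of 81 transcription regulator genes, 25 were higher, 24 lower and 32 not called, or 25 and 24 adjusted over the list alone. For transcription regulator genes, camera gave adjusted p = 0.72. Of 8 archaellum and pili genes, 3 were higher, 0 lower and 5 not called, or 3 and 0 adjusted over the list alone. For archaellum and pili genes, camera gave adjusted p = 0.48. Of 48 central carbon genes, 15 were lower, 8 higher and 25 not called, or 14 and 8 adjusted over the list alone. For central carbon genes, camera gave adjusted p = 0.43. Of 47 respiration and ATP synthesis genes, 18 were lower, 12 higher and 17 not called, or 18 and 12 adjusted over the list alone. For respiration and ATP synthesis genes, camera gave adjusted p = 0.52.

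At 12 h the same sulfur-oxidation cluster stood lowest, and genes of acyl-CoA metabolism joined those of sulfate assimilation at the top. Transcripts of SiL_0985 (-5.60 ± 0.18), SiL_0978 (-5.19 ± 0.30), SiL_0979 (-5.13 ± 0.26), SiL_0981 (-5.08 ± 0.19) and SiL_0980 (-5.03 ± 0.19) differed most, with SiL_0979 at 79.0 ± 2.81 CPM against 2759 ± 1067. SiL_0977 (-4.97 ± 0.28), SiL_0984 (-4.81 ± 0.17), SiL_0976 (-4.13 ± 0.21), SiL_0071 (-3.86 ± 0.54) and the peroxiredoxin SiL_0983 (-3.70 ± 0.12) were the other genes among the 10 lowest. For SiL_0071 the call was lost in a fit of only the 4 libraries of 12 h (-3.87, adjusted p = 0.078, against 7.7e-12 to 0.078 over all alternatives), and the fold change ran from -4.47 to -2.64 when 1 library was left out. At the top stood gp21 itself and the sulfate assimilation genes SiL_2267 (4.49 ± 0.25), SiL_2268 (4.45 ± 0.20) and SiL_2269 (4.04 ± 0.15), with their undescribed neighbour SiL_2266 (3.92 ± 0.27). These 4 genes were already higher at 0 h, SiL_2266 by 2.96 ± 0.20 and the others by 3.33 to 3.52, and from 0 to 12 h the difference rose by 1.17 ± 0.32 for SiL_2267 (adjusted p = 0.0077). The rises of SiL_2266 (0.96 ± 0.35), SiL_2268 (0.94 ± 0.26) and SiL_2269 (0.52 ± 0.19) passed as well, and these calls were lost when some single libraries were left out (adjusted p up to 0.14, 0.076 and 0.099). The run SiL_0749 to SiL_0752 followed, where the acetyl-CoA acetyltransferases SiL_0750 and SiL_0749 were at 3.95 ± 0.18 and 3.68 ± 0.16, and SiL_0752 and SiL_0751 at 3.96 ± 0.15 and 3.61 ± 0.16. SiL_0750 reached 1134 ± 227 CPM with gp21 against 73.7 ± 8.60 CPM without it. Among genes of 100 CPM or more with gp21, gp21 itself aside, SiL_0752 had the lowest control level, at 6.44% of that with gp21. SiL_2267, SiL_2268 and SiL_2269 had larger fold changes and so lay under 100 CPM with gp21, with low control counts. A PIN-domain gene, SiL_0631, was higher at 3.56 ± 0.38. Division genes were below control, with cdvB (SiL_1170) at -2.16 ± 0.12, cdvC (SiL_1171) at -2.24 ± 0.10, SiL_1195 at -1.68 ± 0.11, SiL_1169 at -1.56 ± 0.13, SiL_1391 at -1.20 ± 0.14 and SiL_1541 at -0.76 ± 0.094. For cdvB this was 226 ± 43.1 CPM against 1007 ± 61.0 CPM. The adjusted p of these division genes was at most 1.9e-05. Among the initiator genes, SiL_1733 was lower (-1.61 ± 0.085), SiL_0002 was higher (0.46 ± 0.14), and SiL_1228 differed by 0.12 ± 0.11 without passing the test (adjusted p = 0.40). The SiL_0002 call was lost without gp21 replicate 1 (adjusted p = 0.18) or without control replicate 1 (adjusted p = 0.055), with 8.5e-04 to 0.18 over all alternatives and a fold change of 0.21 to 0.68 when 1 library was left out.

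In all, 719 genes were higher and 719 lower at 12 h, with 228 and 195 at an absolute log2 fold change of 1 or more. With total counts the median shifted by 0.12 and the split was 870 to 586.

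**Figure D2:**
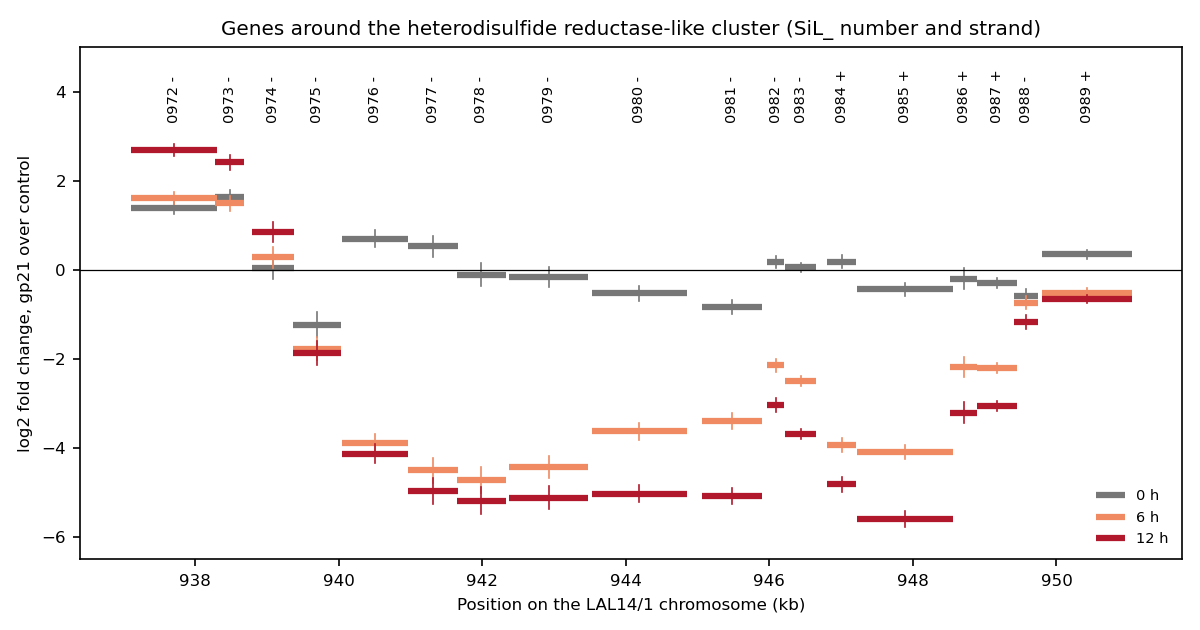
Log2 fold change of gp21 over control along the chromosome around the heterodisulfide reductase-like cluster, from SiL_0972 to SiL_0989; horizontal bars span each gene, thin vertical lines are ± 1 SE, and colours mark 0, 6 and 12 h. Genes SiL_0976 to SiL_0987 lay below control at 6 and 12 h, with -5.60 for SiL_0985 at 12 h, while at 0 h SiL_0979 differed by -0.16, SiL_0976 by 0.70 and SiL_0981 by -0.83.

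Of the lists at 12 h, cell division, DNA replication, nucleotide synthesis and DNA repair were lower. Of 6 cell division genes, 6 were lower, 0 higher and 0 not called, or 6 and 0 adjusted over the list alone. For cell division genes, camera gave adjusted p = 1.3e-04, and adjusted p = 0.55 with an estimated correlation. Of 25 DNA replication genes, 14 were lower, 3 higher and 8 not called, or 15 and 3 adjusted over the list alone. For DNA replication genes, camera gave adjusted p = 0.0065, and adjusted p = 0.55 with an estimated correlation. SiL_1226 was at -1.85 ± 0.18 and the B-family polymerase SiL_0654 at -0.98 ± 0.10. Of 29 nucleotide synthesis genes, 16 were lower, 6 higher and 7 not called, or 16 and 6 adjusted over the list alone. For nucleotide synthesis genes, camera gave adjusted p = 0.022, and adjusted p = 0.55 with an estimated correlation. The gene purS (SiL_1383) was at -2.24 ± 0.15 and dCTP deaminase SiL_1798 at -1.55 ± 0.11, but ribonucleotide reductase SiL_1153 was higher at 1.16 ± 0.11. Of 32 DNA repair and exchange genes, 13 were lower, 2 higher and 17 not called, or 11 and 2 adjusted over the list alone. For DNA repair and exchange genes, camera gave adjusted p = 0.024, and adjusted p = 0.55 with an estimated correlation. The HerA-type SiL_0095 was at -1.74 ± 0.095 and nurA (SiL_0094) at -1.80 ± 0.12. Of 6 chromosome organisation genes, 4 were lower, 0 higher and 2 not called, or 4 and 0 adjusted over the list alone. For chromosome organisation genes, camera gave adjusted p = 0.069. Without exclusions by hand the last p was 0.049.

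Respiration, CRISPR-Cas, fatty acid and transposase genes were higher at 12 h. Of 47 respiration and ATP synthesis genes, 31 were higher, 11 lower and 5 not called, or 31 and 11 adjusted over the list alone. For respiration and ATP synthesis genes, camera gave adjusted p = 0.0065, and adjusted p = 0.55 with an estimated correlation. Quinol oxidase genes SiL_2232 (2.57 ± 0.11) and SiL_2233 (2.28 ± 0.11), the Rieske protein SiL_2230 (2.38 ± 0.12) and cytochrome b SiL_2231 (2.40 ± 0.11) led that list. Of 28 CRISPR-Cas genes, 16 were higher, 5 lower and 7 not called, or 16 and 6 adjusted over the list alone. For CRISPR-Cas genes, camera gave adjusted p = 0.0082, and adjusted p = 0.55 with an estimated correlation. The csc1 gene SiL_0607 was at 1.96 ± 0.11 and cas6 (SiL_0385) at 1.65 ± 0.13, and the list's call ended without exclusions by hand (adjusted p = 0.058). Of 52 fatty acid and acyl-CoA genes, 24 were higher, 7 lower and 21 not called, or 24 and 7 adjusted over the list alone. For fatty acid and acyl-CoA genes, camera gave adjusted p = 0.016, and adjusted p = 0.55 with an estimated correlation. The AMP-forming acyl-CoA synthetase SiL_0300 was at 1.75 ± 0.12. Of 27 transposase genes, 13 were higher, 2 lower and 12 not called, or 15 and 2 adjusted over the list alone. For transposase genes, camera gave adjusted p = 0.049, and adjusted p = 0.55 with an estimated correlation. The transposase call was lost without exclusions by hand (adjusted p = 0.051) and with the replicate number as a block (adjusted p = 0.055).

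Ribosomal protein genes, lower at 6 h, had a median of 0.16 at 12 h and were not called as a list. Of 66 ribosomal protein genes, 13 were higher, 4 lower and 49 not called, or 9 and 3 adjusted over the list alone. For ribosomal protein genes, camera gave adjusted p = 0.080. Of 35 translation factor and tRNA ligase genes, 5 were higher, 5 lower and 25 not called, or 4 and 4 adjusted over the list alone. For translation factor and tRNA ligase genes, camera gave adjusted p = 0.89. Of 49 amino acid synthesis genes, 16 were higher, 16 lower and 17 not called, or 16 and 17 adjusted over the list alone. For amino acid synthesis genes, camera gave adjusted p = 0.57. Of 25 transcription machinery genes, 5 were lower, 4 higher and 16 not called, or 4 and 4 adjusted over the list alone. For transcription machinery genes, camera gave adjusted p = 0.93. Of 81 transcription regulator genes, 30 were lower, 21 higher and 30 not called, or 30 and 21 adjusted over the list alone. For transcription regulator genes, camera gave adjusted p = 0.52. Of 39 toxin-antitoxin genes, 16 were higher, 5 lower and 18 not called, or 16 and 5 adjusted over the list alone. For toxin-antitoxin genes, camera gave adjusted p = 0.069. Of 8 archaellum and pili genes, 5 were lower, 1 higher and 2 not called, or 5 and 1 adjusted over the list alone. For archaellum and pili genes, camera gave adjusted p = 0.12. Of 48 central carbon genes, 27 were higher, 11 lower and 10 not called, or 29 and 11 adjusted over the list alone. For central carbon genes, camera gave adjusted p = 0.11.

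Genes seen at both times were compared directly, and the 6 h and 12 h comparisons share no library. Both contrast the same strains, so a lasting strain difference would enter both, and the lists are not independent in that sense. In the same direction, 425 genes were higher and 391 lower at both times, where independent lists of these sizes would share 225 and 206 (Fisher's exact test, one-sided, p = 1.8e-76 and 9.2e-68, genes not being independent). Another 170 genes were called in opposite directions, 98 of them higher at 6 h and lower at 12 h. Of the 425 and 391 genes, 139 and 145 had not been called at 0 h, 186 and 139 had been called in the same direction at 0 h, and 100 and 107 in the opposite one. For 216 and 244 of them the change of the difference from 0 h was also called in that direction at both times, and cdvB, cdvC, SiL_1169 and SiL_1195 were among these lower genes. In the authors' deposited table, which pools 6 and 12 h, 544 genes were higher and 516 lower at an adjusted p under 0.05, and 790 of the 816 genes above had such a value there in the same direction. The authors' deposited table gave log2 fold changes of -2.52 for cdvB (SiL_1170), -2.49 for cdvC (SiL_1171) and 4.18 for gp21.

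The strains already differed at 0 h, among them in a nitrate reductase gene, the sulfate assimilation genes above, amino acid transporter genes, ribosomal protein genes and genes of unknown function. SiL_1493, which has no described function, stood at 15856 ± 608 CPM with the gp21 plasmid and 127 ± 5.23 CPM without it (6.96 ± 0.14), and SiL_2112, also undescribed, was higher by 5.15 ± 0.13. An amino acid transporter gene, SiL_0726, was higher (4.56 ± 0.13), whereas another, SiL_0892, was lower (-3.89 ± 0.10). The nitrate reductase alpha gene SiL_0479 was lower (-5.09 ± 0.19), at 171 ± 17.0 CPM against 5832 ± 149, and so was SiL_2338 (-3.79 ± 0.26). The division genes cdvB (SiL_1170, -0.11 ± 0.12, adjusted p = 0.41) and cdvC (SiL_1171, -0.15 ± 0.095, adjusted p = 0.17) did not pass the test, while SiL_1195 (-0.71 ± 0.11), SiL_1541 (-0.79 ± 0.094) and SiL_1391 (-0.89 ± 0.14) were lower. SiL_1169 was higher at 0.40 ± 0.13, a call lost without control replicate 1 (adjusted p = 0.10) or gp21 replicate 2 (adjusted p = 0.085), and with total counts (0.25, adjusted p = 0.11, the range over all alternatives being 5.7e-04 to 0.11). With total counts cdvC (SiL_1171) passed the test (-0.31, adjusted p = 0.0084, against 0.0084 to 0.47 over all alternatives). In the heterodisulfide reductase-like region SiL_0976 to SiL_0987, SiL_0976 was higher at 0 h (0.70 ± 0.19), and SiL_0980 (-0.53 ± 0.16), SiL_0981 (-0.83 ± 0.16), SiL_0985 (-0.44 ± 0.15) and SiL_0987 (-0.30 ± 0.11) were lower. The calls of SiL_0980, SiL_0985 and SiL_0987 were lost when some single libraries were left out (adjusted p up to 0.053, 0.093 and 0.15). The initiator genes SiL_1733 (-1.17 ± 0.084) and SiL_0002 (-0.87 ± 0.14) were lower and SiL_1228 was higher (0.52 ± 0.11).

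The 0 h test called 882 genes higher and 893 lower, 226 and 361 of them with an absolute log2 fold change of 1 or more. Total counts shifted the median by -0.15 and gave 696 higher and 1046 lower. The authors' deposited table for 0 h listed 1651 genes with an unadjusted p under 0.05.

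Ribosomal protein genes had the smallest adjusted p of the lists at 0 h, with a median of 0.98, and the list of other replicons or viruses had the median furthest from 0 among the lists called (-1.16). Of 66 ribosomal protein genes, 60 were higher, 1 lower and 5 not called, or 60 and 1 adjusted over the list alone. For ribosomal protein genes, camera gave adjusted p = 1.1e-11, and adjusted p = 0.55 with an estimated correlation. L7Ae (SiL_1885) was at 1.87 ± 0.12 and L3 (SiL_1278) at 1.30 ± 0.11. Of 35 translation factor and tRNA ligase genes, 22 were higher, 4 lower and 9 not called, or 22 and 4 adjusted over the list alone. For translation factor and tRNA ligase genes, camera gave adjusted p = 9.7e-04, and adjusted p = 0.55 with an estimated correlation. Threonyl-tRNA synthetase SiL_0269 was at 1.16 ± 0.10. Of 49 amino acid synthesis genes, 30 were higher, 3 lower and 16 not called, or 30 and 3 adjusted over the list alone. For amino acid synthesis genes, camera gave adjusted p = 1.2e-04, and adjusted p = 0.55 with an estimated correlation. The lysine gene SiL_1105 (homocitrate synthase) was higher at 2.93 ± 0.10, and argininosuccinate lyase SiL_1374 lower at -3.57 ± 0.18. Of 47 respiration and ATP synthesis genes, 28 were higher, 8 lower and 11 not called, or 28 and 8 adjusted over the list alone. For respiration and ATP synthesis genes, camera gave adjusted p = 0.0061, and adjusted p = 0.55 with an estimated correlation. The hydrogenase-like genes SiL_1080 and SiL_1081 were at 1.70 ± 0.13 and 1.64 ± 0.10. Of 25 transcription machinery genes, 14 were higher, 4 lower and 7 not called, or 14 and 4 adjusted over the list alone. For transcription machinery genes, camera gave adjusted p = 0.024, and adjusted p = 0.55 with an estimated correlation. Without exclusions by hand that call was lost (adjusted p = 0.17). Of 27 transposase genes, 18 were higher, 6 lower and 3 not called, or 18 and 6 adjusted over the list alone. For transposase genes, camera gave adjusted p = 0.035, and adjusted p = 0.55 with an estimated correlation.

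Transcription regulators and genes of other replicons were lower at 0 h. Of 81 transcription regulator genes, 39 were lower, 19 higher and 23 not called, or 39 and 19 adjusted over the list alone. For transcription regulator genes, camera gave adjusted p = 0.045, and adjusted p = 0.67 with an estimated correlation. Against that direction, the GntR-type SiL_0469 was higher at 1.81 ± 0.14. Of 7 replicon or virus genes, 7 were lower, 0 higher and 0 not called, or 7 and 0 adjusted over the list alone. For replicon or virus genes, camera gave adjusted p = 0.0065, and adjusted p = 0.55 with an estimated correlation. Among them were the conjugative plasmid gene SiL_1321 (-2.74 ± 0.16) and the SSV-like gene SiL_2368 (-2.57 ± 0.25). Of 7 replicon or virus genes, 2 were higher, 0 lower and 5 not called at 6 h, or 2 and 0 adjusted over the list alone. For replicon or virus genes, camera gave adjusted p = 0.43. Of 7 replicon or virus genes, 1 was lower, 0 higher and 6 not called at 12 h, or 1 and 0 adjusted over the list alone. For replicon or virus genes, camera gave adjusted p = 0.48. The lists that follow were not called at 0 h. Of 6 cell division genes, 3 were lower, 1 higher and 2 not called, or 3 and 1 adjusted over the list alone. For cell division genes, camera gave adjusted p = 0.24. Of 25 DNA replication genes, 11 were lower, 5 higher and 9 not called, or 11 and 5 adjusted over the list alone. For DNA replication genes, camera gave adjusted p = 0.23. Of 29 nucleotide synthesis genes, 15 were higher, 8 lower and 6 not called, or 15 and 9 adjusted over the list alone. For nucleotide synthesis genes, camera gave adjusted p = 0.37. Of 6 chromosome organisation genes, 2 were higher, 1 lower and 3 not called, or 2 and 1 adjusted over the list alone. For chromosome organisation genes, camera gave adjusted p = 0.89. Of 32 DNA repair and exchange genes, 14 were lower, 6 higher and 12 not called, or 13 and 6 adjusted over the list alone. For DNA repair and exchange genes, camera gave adjusted p = 0.43. Of 8 archaellum and pili genes, 7 were lower, 1 higher and 0 not called, or 7 and 1 adjusted over the list alone. For archaellum and pili genes, camera gave adjusted p = 0.080. Of 28 CRISPR-Cas genes, 12 were higher, 3 lower and 13 not called, or 10 and 3 adjusted over the list alone. For CRISPR-Cas genes, camera gave adjusted p = 0.15. Of 39 toxin-antitoxin genes, 15 were lower, 10 higher and 14 not called, or 14 and 10 adjusted over the list alone. For toxin-antitoxin genes, camera gave adjusted p = 0.58. Of 48 central carbon genes, 17 were higher, 14 lower and 17 not called, or 17 and 14 adjusted over the list alone. For central carbon genes, camera gave adjusted p = 0.80. Of 52 fatty acid and acyl-CoA genes, 24 were higher, 15 lower and 13 not called, or 24 and 15 adjusted over the list alone. For fatty acid and acyl-CoA genes, camera gave adjusted p = 0.53.

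Several lists held genes that moved both ways and were called at none of the 3 times. Of 59 pentose and sugar genes, 23 were higher, 16 lower and 20 not called at 0 h, or 23 and 16 adjusted over the list alone. For pentose and sugar genes, camera gave adjusted p = 0.39. Of 59 pentose and sugar genes, 20 were lower, 17 higher and 22 not called at 6 h, or 20 and 17 adjusted over the list alone. For pentose and sugar genes, camera gave adjusted p = 0.58. Of 59 pentose and sugar genes, 21 were lower, 17 higher and 21 not called at 12 h, or 22 and 18 adjusted over the list alone. For pentose and sugar genes, camera gave adjusted p = 0.83. The sugar transport gene SiL_2438 was at 1.51 ± 0.091 at 6 h and 2.05 ± 0.093 at 12 h. Of 15 protein quality control genes, 8 were higher, 4 lower and 3 not called at 0 h, or 8 and 4 adjusted over the list alone. For protein quality control genes, camera gave adjusted p = 0.48. Of 15 protein quality control genes, 8 were lower, 3 higher and 4 not called at 6 h, or 8 and 3 adjusted over the list alone. For protein quality control genes, camera gave adjusted p = 0.22. Of 15 protein quality control genes, 4 were lower, 3 higher and 8 not called at 12 h, or 4 and 3 adjusted over the list alone. For protein quality control genes, camera gave adjusted p = 0.58. The proteasome-activating gene SiL_1720 was lower each time, at -1.18 ± 0.10, -1.07 ± 0.10 and -1.58 ± 0.11. Of 23 oxidative stress genes, 9 were higher, 5 lower and 9 not called at 0 h, or 9 and 5 adjusted over the list alone. For oxidative stress genes, camera gave adjusted p = 0.43. Of 23 oxidative stress genes, 9 were higher, 6 lower and 8 not called at 6 h, or 9 and 8 adjusted over the list alone. For oxidative stress genes, camera gave adjusted p = 0.82. Of 23 oxidative stress genes, 12 were higher, 6 lower and 5 not called at 12 h, or 12 and 6 adjusted over the list alone. For oxidative stress genes, camera gave adjusted p = 0.53. Rubrerythrin SiL_2511 was higher at 12 h (1.81 ± 0.11).

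Surface layer and sulfur lists were not called either, although the sulfur list holds members of both the lowest and the highest clusters. Of 51 surface layer and lipid genes, 16 were higher, 15 lower and 20 not called at 0 h, or 16 and 15 adjusted over the list alone. For surface layer and lipid genes, camera gave adjusted p = 0.93. Of 51 surface layer and lipid genes, 14 were lower, 13 higher and 24 not called at 6 h, or 14 and 13 adjusted over the list alone. For surface layer and lipid genes, camera gave adjusted p = 0.86. Of 51 surface layer and lipid genes, 8 were higher, 8 lower and 35 not called at 12 h, or 8 and 6 adjusted over the list alone. For surface layer and lipid genes, camera gave adjusted p = 0.99. SlaA (SiL_1604) was lower at 6 h (-0.76 ± 0.16). Of 122 sulfur and metal genes, 36 were lower, 33 higher and 53 not called at 0 h, or 36 and 32 adjusted over the list alone. For sulfur and metal genes, camera gave adjusted p = 0.83. Of 122 sulfur and metal genes, 33 were higher, 30 lower and 59 not called at 6 h, or 32 and 29 adjusted over the list alone. For sulfur and metal genes, camera gave adjusted p = 0.97. Of 122 sulfur and metal genes, 35 were lower, 32 higher and 55 not called at 12 h, or 35 and 32 adjusted over the list alone. For sulfur and metal genes, camera gave adjusted p = 0.66. Median, mean and test differed in sign for 11 of the 69 list tests, none of them called. These were chromosome organisation, central carbon and fatty acid metabolism at 0 h, respiration and sulfur handling at 6 h, oxidative stress at 6 and 12 h, translation at 12 h and the surface layer list at all 3 times. Of the 69 list tests, 27 passed with the preset correlation, 0 with an estimated one (smallest adjusted p = 0.55) and 44 by the directional fry test.

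The change over time of the difference between the strains was tested as the difference of differences. From 0 to 6 h the difference between the strains rose most in SiL_2338 (5.94 ± 0.33), SiL_0508 (5.15 ± 0.29) and the mercury resistance gene merI (SiL_2461, 5.12 ± 0.30), and fell most in SiL_1493 (-6.97 ± 0.16), SiL_2112 (-5.13 ± 0.17) and the heterodisulfide reductase-like gene SiL_0977 (-5.03 ± 0.36). For merI the mean level with gp21 went from 82.3 to 552 and 65.5 CPM, and in control from 599.7 to 115 and 217 CPM. Among division genes it fell for cdvB (SiL_1170, -2.99 ± 0.17), cdvC (SiL_1171, -2.65 ± 0.14) and SiL_1195 (-1.81 ± 0.15), with adjusted p at most 5.3e-07. From 0 to 12 h the difference rose most in SiL_0753 (5.52 ± 0.38), SiL_0752 (4.19 ± 0.20) and SiL_0750 (4.10 ± 0.24). It fell most in SiL_1493 (-6.70 ± 0.16), SiL_2112 (-5.61 ± 0.17) and SiL_0977 (-5.49 ± 0.37). Between 6 and 12 h it rose most in SiL_2191 (3.15 ± 0.24), thiazole-adenylate synthase SiL_1558 (2.42 ± 0.19) and succinyl-CoA synthetase SiL_0266 (2.29 ± 0.28), and fell most in SiL_0732 (-4.01 ± 0.21), merI (-3.99 ± 0.29) and the efflux permease SiL_0285 (-3.82 ± 0.35). In counts, the difference changed for 1819 genes from 0 to 6 h (924 up, 895 down), for 1461 from 0 to 12 h (752 up, 709 down) and for 1112 from 6 to 12 h (557 up, 555 down). With total counts these splits became 1251 to 568, 1038 to 448 and 430 to 641.

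Over time, the arabinose genes SiL_2145, SiL_2089 and SiL_2144 rose in both strains by 12 h, while gene lists were not tested over time. The nitrate transporter gene SiL_0480 fell most in both strains at 6 and 12 h. It went from 2951 ± 52.4 to 5.40 ± 1.07 CPM by 6 h in control (-9.10 ± 0.17) and from 540.3 ± 44.4 to 4.29 ± 0.239 CPM with gp21 (-6.98 ± 0.16). SiL_0663 fell alongside it in control (-7.69 ± 0.18) and with gp21 (-6.61 ± 0.17), as did the membrane protein gene SiL_0693 in control (-7.98 ± 0.19) and the radical SAM gene SiL_0778 with gp21 (-6.33 ± 0.15). By 12 h the values for SiL_0480 were -9.14 ± 0.17 in control and -7.69 ± 0.17 with gp21, for SiL_0663 they were -7.48 ± 0.18 and -6.46 ± 0.17, and SiL_0693 in control and SiL_0667 with gp21 stood at -7.65 ± 0.18 and -7.07 ± 0.19. The ammonium transporter gene SiL_1047 rose in control by 4.63 ± 0.22 at 6 h and 3.98 ± 0.21 at 12 h, and with gp21 by 3.97 ± 0.22 at 6 h. In control the sulfide-quinone oxidoreductase SiL_0071 (4.80 ± 0.56) and SiL_0977 (3.89 ± 0.27) rose most besides it at 6 h, and SiL_0976 (3.75 ± 0.21) and SiL_0977 (3.72 ± 0.26) at 12 h. With gp21, by contrast, SiL_0977 changed by -1.14 ± 0.25 at 6 h and -1.77 ± 0.26 at 12 h (adjusted p = 0.0011 and 7.6e-05). In that strain the arabinose-binding protein SiL_2145 (3.28 ± 0.11), D-arabinonate dehydratase SiL_2089 (3.20 ± 0.15) and the arabinose transporter SiL_2144 (3.09 ± 0.29) rose most by 12 h, with rises in control of 2.49 ± 0.10, 3.01 ± 0.15 and 1.82 ± 0.27, and SiL_2338 (4.30 ± 0.26) and the tRNA gene SiL_t0006 (4.08 ± 0.19) by 6 h. In control, 894 genes rose and 893 fell from 0 to 6 h, and 795 rose and 790 fell from 0 to 12 h. With gp21, 943 rose and 987 fell by 6 h, and 810 rose and 813 fell by 12 h, where total counts gave 1422 and 599, and 1287 and 493.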

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

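All tests of explanations in this part were chosen after the results they bear on were seen, except that of lists matched on expression level; the tests of differences between times were planned. The difference between gp21 and control changed between times in the genes below by the interaction test of edgeR.

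From 0 to 6 h it rose for SiL_2338 (5.94), SiL_0508 (5.15), merI SiL_2461 (5.12), the initiator gene SiL_0002 (1.37) and SiL_0190 (1.06). It fell for SiL_1493 (-6.97), SiL_2112 (-5.13) and the heterodisulfide reductase-like SiL_0977 (-5.03). Division genes went down in that interval, with cdvB SiL_1170 at -2.99, cdvC SiL_1171 at -2.65, SiL_1169 at -2.59, SiL_1195 at -1.81, SiL_1391 at -0.67 and SiL_1541 at -0.64, as did the initiator genes SiL_1228 (-0.97) and SiL_1733 (-0.34). With total counts the calls of SiL_1391 (-0.28, adjusted p = 0.28), SiL_1541 (-0.25, adjusted p = 0.13) and SiL_1733 (0.051, adjusted p = 0.75, of opposite sign) were lost, that of SiL_1733 also when some single libraries were left out (adjusted p up to 0.068).

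From 0 to 12 h it rose for SiL_0753 (5.52), SiL_0752 (4.19), SiL_0750 (4.10), gp21 (1.51) and SiL_0002 (1.34). It fell for SiL_1493 (-6.70), SiL_2112 (-5.61), SiL_0977 (-5.49), SiL_1171 (-2.09), SiL_1170 (-2.04), SiL_1169 (-1.96), SiL_1195 (-0.97), SiL_1733 (-0.44) and SiL_1228 (-0.40). The calls of the last 2 were lost with total counts (adjusted p = 0.32 and 0.56) and when some single libraries were left out, and that of SiL_1228 also with DESeq2 (adjusted p = 0.054). For gp21, mean CPM went from 68.3 to 113 with the gp21 plasmid and from 8.14 to 4.72 in control. Part of its rise thus came from the control counts, which are uncertain. Within the gp21 strain the change from 0 to 12 h was 0.32 without gp21 replicate 2 of 12 h.

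From 6 to 12 h it rose for SiL_2191 (3.15), SiL_1558 (2.42) and SiL_0266 (2.29), and by less for SiL_1170 (0.95), SiL_1195 (0.84), SiL_1541 (0.67), SiL_1169 (0.63), SiL_1228 (0.57) and SiL_1171 (0.57). The SiL_1228 call was lost with total counts (adjusted p = 0.052). The difference fell for SiL_0732 (-4.01), SiL_2461 (-3.99), SiL_0285 (-3.82) and SiL_0190 (-1.24).

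The gp21 transcript was counted in control libraries, at 11.9%, 7.73% and 4.19% of its level with the gp21 plasmid at 0, 6 and 12 h. Carry-over of reads from the gp21 libraries would bring every abundant transcript along, and at 0 h 3 of 1280 genes of 100 CPM or more lay in control at less than 0.5 of that share, the lowest being SiL_1493 at 0.801%, which argues against carry-over there; the bound of 3 genes was set after these values were seen and is met exactly. At 6 and 12 h the number was 0, so carry-over from the gp21 libraries cannot be told apart from other sources at those times. Reads shared with the host homologue SiL_0190 may contribute: the ratio of gp21 to SiL_0190 varied less over the 6 control libraries than that to 94.0% of other genes, just under the bound of 95%, with 7.20 to 12.4 gp21 counts per 100 of SiL_0190, and without the sequences this stays open. No biological explanation was tested.

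The strains differed at 0 h in 1775 genes. The choice of TMM over total counts is argued against as the source of most of these calls, since 89.5% were called in the same direction with total counts. The split still moved from 882 higher and 893 lower to 696 and 1046. Both scalings are relative, so a change in the total amount of RNA is not covered. Cultures at different points of the control time course cannot be told apart from other traits of the control cultures at 0 h. The covariance over genes of the 0 h difference with the control change from 0 to 6 h was 0.361. The highest value in 20 simulations of unchanged groups was 0.0179. Both contrasts hold the same 2 control libraries of 0 h, so any trait of these raises the covariance. The correlation was 0.35, against a mean of 0.50 in the simulations. Those simulations hold spread between libraries alone and no real changes, so neither simulated value can decide the question. Genes SiL_1169 to SiL_1171 had a median of -0.11 at 0 h against -2.81 at 6 h. The gp21 transcript was at 68.3 and 63.7 CPM (a change of 0.38 with total counts). This argues against a lowering that follows the transcript level in these 3 genes. It does not bear on the other genes that differed at 0 h. The gp21 protein was not measured, so a like transcript level need not mean a like protein level. Whether gp21 lowered the other 3 ESCRT-III genes at 0 h stays open, since their median was -0.79 against -1.56. Of them 2, SiL_1391 and SiL_1541, were at least 0.5 times as far below control at 0 h as at 6 h. The median of these 6 genes (-0.43 at 0 h, -2.36 at 6 h) was the first test of the transcript already present at 0 h, and for the 1775 genes it was replaced, after its value was seen, by the sign of their differences. For these the transcript stays open, since 41.1% had the same sign of difference at 6 h and 67.5% at 12 h, which point different ways. Strain background and plasmid cannot be separated from these, since they coincide in all libraries, whatever the number (2 control and 2 gp21 libraries at 0 h).

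Ribosomal protein genes were higher at 0 h (median 0.98) and lower at 6 h (-0.58). Scaling moves all genes of a comparison alike and is argued against, as 97.0% of these genes lay above the median of the other tested genes at 0 h and 92.4% below it at 6 h; with total counts their medians were 0.83 and -0.35. A trend with expression level is argued against by 10000 lists matched on mean expression, of which 0% had a median as far from 0 at either time. Those lists drew genes singly, while the estimated correlation between the ribosomal protein genes was 0.32, so the 0% is no p-value for the list. The list was picked for its calls in these data, and camera with the estimated correlation gave adjusted p = 0.55 at 0 and 6 h. A median below control that follows the gp21 transcript is argued against by the 12 h median of 0.16, when that transcript was at least as high. Set against the 0.98 of 0 h, the medians of 6 and 12 h were both lower. An effect of gp21 on top of the 0 h difference therefore stays open. A difference in growth state between the cultures remains untested.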

How the results depend on the processing

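Total counts without SlaA and lists without exclusions by hand were chosen only after the results were seen, and the other alternatives were planned. With an absolute log2 fold change of 1 or more, 241 genes were higher and 208 lower at 6 h, 228 and 195 at 12 h and 226 and 361 at 0 h. That requirement left 1058, 673 and 380 genes for the differences from 0 to 6, 0 to 12 and 6 to 12 h, 626 and 470 over time in control (6 and 12 h), 899 and 531 with gp21, and 194 genes shared by 6 and 12 h, since it keeps only the larger changes. With total counts 494 genes were lower at 6 h, where the median shift shows the cause. Of the 69 list tests, 27 passed as reported, 0 with an estimated correlation (smallest adjusted p = 0.55), 44 by directional and 69 by mixed fry, and 25 without exclusions by hand, 23 of them shared. Leaving out 1 library at a time, with the remaining one assumed to vary like the other groups, gave 698 to 818 genes higher and 646 to 801 lower at 6 h, 617 to 739 and 608 to 718 at 12 h, and 733 to 904 and 775 to 911 at 0 h. The differences ran from 1650 to 1848, 1227 to 1469 and 927 to 1074, changes over time in control from 1553 to 1826 and 1284 to 1586, and with gp21 from 1735 to 1974 and 1368 to 1680. Of 10061 pairs of a named gene result and an alternative, 9836 kept direction and side of the threshold. Most of these genes were picked for a large fold change or small adjusted p in these data, which favours that. Over all reported calls, total counts kept 83.6%, 90.7% and 89.5% in the same direction at 6, 12 and 0 h. They kept 82.0% for the difference from 0 to 6 h and 79.9% for the change from 0 to 6 h with gp21. Among the named gene pairs, a call was lost in 177. Of those, 103 fell under the required absolute log2 fold change of 1 or more, which drops smaller changes by definition. Another 27 pairs gained a call and 21 changed sign, and the cause of changes under the other alternatives was not tested. Of these 21, SiL_1733 was called as reported, its change of the difference from 0 to 6 h being -0.34, or 0.051 with total counts. The others were SiL_0190 at 6 h (-0.096 without gp21 replicate 2, 0.27 without gp21 replicate 1), SiL_1860 at 6 h (0.024 with total counts, -0.56 to 0.036 without 1 library), SiL_1228 at 12 h (-0.031 to 0.25 without 1 library) and the gp21 transcript from 0 to 6 h with gp21 (0.38 with total counts, 0.20 without SlaA). Also among them were changes of the difference from 0 to 6 h, for SiL_2265 (0.16 with total counts, 0.037 without SlaA), SiL_2267 (0.21 and 0.094, and -0.43 to 0.20 without 1 library), SiL_2269 (-0.0012 in a fit of only the groups compared, -0.13 to 0.13 without 1 library) and SiL_2270 (0.086 with total counts, -0.66 to 0.019 without 1 library). With SlaA left out under total counts, 1039 genes were higher and 591 lower at 6 h, 709 and 710 at 12 h and 729 and 1038 at 0 h. Fits of only the groups compared gave 732 genes higher and 715 lower at 6 h, 631 and 660 at 12 h and 987 and 963 at 0 h. They kept 90.9%, 88.8% and 99.3% of the reported calls at 6, 12 and 0 h. Depth of 17033337 to 22299061 reads and 2 libraries per group limit what is seen of small changes. In the simulations part of the 1.5-fold changes was missed, and smaller ones were not simulated. The promoter motif and its alternatives were not run.

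Whether replicate numbers pair the samples stayed open: of 15 pairs of groups, 6 had deviations correlated over 0.1, with a range of -0.33 to 0.30. Between times the correlations were 0.20, 0.090 and 0.14 in control, and -0.15, -0.13 and 0.19 with gp21. With the replicate number as a block within each plasmid, the difference rose for 934 genes and fell for 897 from 0 to 6 h. From 0 to 12 h these counts were 775 and 734, and from 6 to 12 h 588 and 568. With the number as a replicate block, 829 genes were higher and 756 lower at 6 h, 736 and 723 at 12 h and 896 and 905 at 0 h, and 26 list tests passed, the transposases at 12 h being lost (adjusted p = 0.055).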

Other observations

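The genes in this part were chosen after their values were seen. Transfer RNA genes were not tested as a list. Of 45 tRNA genes, 26 were lower and 3 higher at 0 h (median -0.96), while 20 were higher and 3 lower at 6 h (median 0.47) and 6 were higher and 8 lower at 12 h (median -0.048). Within the gp21 strain 40 rose and 1 fell from 0 to 6 h (median 1.75), against 18 and 5 in control (median 0.21), and from 0 to 12 h 24 rose and 1 fell (median 0.73), against 5 and 9 in control (median -0.093). Transfer RNA took at most 0.15% of the reads.

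Of the V/A-type ATP synthase genes, SiL_1440 was at 0.67 ± 0.11, -0.48 ± 0.11 and 0.68 ± 0.11 at 0, 6 and 12 h and SiL_1445 at 0.76 ± 0.14, -1.64 ± 0.14 and 0.25 ± 0.14, the last not past the test (adjusted p = 0.14). That 12 h value of SiL_1445 ran from 0.11 to 0.43 when 1 library was left out, and it gained a call without control replicate 2 (0.43). For SiL_1440 the 6 h call was lost with total counts (-0.26, adjusted p = 0.062). The branched-chain amino acid transport genes SiL_2307 to SiL_2311 were lower with gp21 at both later times, at -1.70 to -0.84 at 6 h (adjusted p at most 3.5e-04) and -3.18 to -2.77 at 12 h (adjusted p at most 2.0e-08), and were not tested as a list. At 0 h SiL_2308 to SiL_2311 were higher (0.57 to 0.92, adjusted p at most 0.0039) and SiL_2307 was at -0.15 ± 0.10 (adjusted p = 0.22, or 0.012 with total counts).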
